A study of Anser anser with 16 samples.

How the data were processed

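RNA was measured in 16 libraries, from the pituitary and the hypothalamus of 8 male geese at day 108, 4 of them with a low and 4 with a high growth rate, per the labels. RNA came from column extraction with RIN values over 7 and TruSeq v2 libraries, per the labels' protocols. Group and bird were taken from the sample titles, and the titles give the same bird numbers in both tissues. How birds were assigned to a growth rate is not given in the sources used here.

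The authors deposited 4 quantifications of the same libraries. The pair of tables written here as the ENSACDG and the ENSABRG gene tables after the prefix of their gene identifiers, holds whole-number counts of reads per gene, as deposited. The other tables hold estimated counts per gene of a de novo assembly, from kallisto and Salmon per the deposited file names. It is not given whether those estimates were scaled by transcript length. FastQC, STAR, RSEM, DESeq2, kallisto and Salmon are named in the submitters' processing notes, without roles or versions. The only genome build in the submitters' processing notes is a pig assembly, which the gene identifiers and scaffolds in the tables do not carry, so the assembly behind the coordinates is not given in the sources used here. The authors also deposited tables of their own comparison per tissue and quantification, with a fold ratio, its log2 value, and p-values with adjusted p-values, per the file headers. No header names the direction of that ratio. It was taken as low over high growth rate because, once turned, 51 of the 51 genes the authors called in the pituitary and 62 of the 62 in the hypothalamus had the sign of the difference recomputed from the counts. Signs were turned so that every difference reads high minus low, and the columns of group means, which name no group, were not used. For assembled genes the deposited tables also give the best protein match with its percent identity.

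A rule fixed before the data were examined took as the main table the gene-level table with the most named genes passing the expression filter, and, on a tie within 5 percent, the one with the larger median total. The ENSABRG and ENSACDG tables tied at 9922 and 9810 named genes, and the ENSACDG table had the larger median total, 12787828 against 12604692 counts. The de novo tables name genes by protein entry rather than by gene symbol and were not counted as gene-level tables with symbols. Had their 16298 (kallisto) and 15949 (Salmon) protein entry names been counted as symbols, these tables would have tied. The de novo Salmon table, with the larger median total (25038059 against 23537119 estimated counts), would then have been the main one. Both were run as alternatives. Names came from the authors' tables, which named 9810 of the 14394 genes tested over all libraries. Of these names, 9317 were also symbols of a RefSeq annotation of another assembly (bAnsAns1.hap1.1). The choice of the main table was run on such matches, where the ENSABRG and ENSACDG tables also tied, at 9408 and 9317. The de novo kallisto and Salmon tables had 6953 and 6764. That annotation was used for nothing else.

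Totals in the main table were 8543585 to 18068056 counts per library. Libraries of 1 group differed by 8.68 to 82.1 chi-square units per degree of freedom, far beyond sampling noise, so all 16 were kept as separate samples. Counts were filtered with filterByExpr and scaled with TMM. Values in CPM (counts scaled to a common library total) of a growth comparison were scaled within the tissue, and those set across tissues were scaled over all 16 libraries. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 8 libraries of each tissue were fitted by growth group. All 16 libraries were fitted with 4 group means for the difference between tissues, where a fold of at least 2 was also required, and for the interaction of growth rate with tissue. Standard errors of log2 differences came from the quasi-likelihood F statistic. Estimated counts were rounded to whole numbers.

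Lists of genes fixed before the data were examined were tested with camera in limma, at its preset correlation of 0.01, on voom values, for the 38 lists with at least 5 measured members. A further 3 lists had too few. Camera with an estimated correlation and fry were alternatives. A list score is the mean over its members of log2 CPM centred on the tissue, with a prior count of 2, and was compared between groups of 4 birds by a two-sided exact permutation test, whose smallest possible p is 0.0286. Genes are named by a rule fixed in the same way. For growth rate these were up to 10 named genes per direction passing the test without overlap between groups, filled up to 5 by the smallest unadjusted p where fewer passed, together with the hormone and appetite lists and up to 4 members of any other list. For the tissues they were the 10 largest folds per direction with a mean of at least 10 CPM, for the interaction the 5 smallest p per direction, and for the authors' deposited tables the 5 smallest adjusted p. Genes outside that rule are said to have been chosen after their values were seen. Of 28 hormone and neuropeptide protein names sought in the de novo kallisto table after the data were seen, 14 were found. Those values are estimated CPM. A gene that the rule names for the tissues is not reported here.

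The same birds gave both tissues, so the bird numbers pair the libraries across tissues. Deviations from the group means in the 2 tissues of a bird correlated at 0.184 to 0.389 over genes, and all 8 birds correlated best with themselves. The fit with the bird as a block was therefore run for the tissue and interaction comparisons. The alternatives fixed before the data were examined were DESeq2 (1.42.0) size factors, no expression filter, the DESeq2 Wald test, limma voom, the other quantifications, a fit over all 16 libraries, a replicate block, and leaving out each bird. A fit without birds 40 and 50, a fit with the first principal component, the search for assembled hormone genes and a second list of muscle genes were chosen after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

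The tests were tested on simulated counts with the real means and library sizes and 100 genes changed at each fold. At a fold of 2, 44% were recovered in the pituitary growth comparison (13323 genes run), 78% in the hypothalamus (13598), 43% in the interaction (14202) and 83% in the tissue comparison (14200). At a fold of 4 the shares were 87%, 100%, 80% and 99%. False calls among the unchanged genes numbered 6, 10, 10 and 12. In the simulated lists, 10 of 10 raised by 0.3 on the log2 scale were recovered in each tissue, with 0 false calls by camera. The simulated genes were drawn independently, so the count of false calls does not carry over to real lists, whose genes move together. Differences shared by many genes of a bird were not simulated, so the recovered shares need not hold in the real comparisons. With that many changed genes the adjusted threshold is also easier to reach.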

Results

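The hypothalamus and the pituitary were profiled by RNA sequencing in 8 male geese of a White Kołuda strain, to ask what differs along the axis between birds of low and high growth rate. The hypothalamus is the brain region that steers the pituitary through releasing hormones, and the pituitary secretes growth hormone, prolactin, the gonadotropins, thyrotropin and corticotropin. Each of the 4 groups held 4 libraries, from birds 33, 37, 38 and 40 at low and birds 49, 50, 52 and 54 at high growth rate. Library totals ran from 11175363 to 14456667 counts in the pituitary at low and from 8543585 to 13464132 at high growth rate. In the hypothalamus they ran from 9186728 to 11346496 and from 11121872 to 18068056. The 10 most abundant genes took a median of 19.9% and 20.8% of pituitary counts, and 4.13% and 4.16% of hypothalamus counts, at low and high growth rate.

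The 2 tissues were set apart first, as a check of the labels. The pituitary carried the hormone genes. PRL (prolactin) was higher there by 10.94 ± 0.43 on the log2 scale (SE), at 25306 ± 11015 CPM (SD, n = 8) against 13.4 ± 8.38 CPM in the hypothalamus. CGA, the common subunit of the glycoprotein hormones, was higher by 10.41 ± 0.49 and POMC, the precursor of corticotropin, by 8.37 ± 0.24. POU1F1, the transcription factor of somatotrophs, lactotrophs and thyrotrophs, was higher by 8.52 ± 0.18, and AVPR1B, the receptor through which vasotocin-type peptides act on corticotrophs in mammals, by 7.69 ± 0.17. The hypothalamus carried glial and neuronal genes. The pituitary differed from it by -8.14 ± 0.75 in GFAP, the astrocyte intermediate filament, by -6.36 ± 0.15 in AQP4, the astrocyte water channel, and by -6.26 ± 0.16 in SLC17A6, a vesicular glutamate transporter of neurons. Adjusted p-values of these genes in edgeR ran from 3.85e-15 for POU1F1 to 5.48e-08 for GFAP.

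In all, 4948 of 14394 genes differed between the tissues at an adjusted p under 0.05 and a fold of at least 2 (edgeR), 2148 of them higher in the pituitary and 2800 in the hypothalamus. Other genes among the 10 largest folds were ALDH1A3, ALDH1A1, SIX2, CHGA and ESRP2, higher in the pituitary by 6.51 to 7.51, and PHGDH, SLC6A11, LGI3, CHL1, SNCG and AGT, higher in the hypothalamus with differences of -7.64 to -5.98. Of the fixed lists, 11 differed by camera. Pituitary endocrine cell genes were higher in the pituitary, with 9 of 11 members at least 2-fold higher, and neuronal genes in the hypothalamus, with 12 of 13. Both lists held with an estimated correlation, each at an adjusted p of 0.00586 by limma's camera. Also higher in the pituitary were cytoplasmic ribosomal proteins, 37 of 56 at that fold (8.16e-18), and the unfolded protein response, 10 of 20 (1.77e-05), with adjusted p = 0.238 and 0.391 with an estimated correlation. Higher in the hypothalamus were GABA and glutamate synapses, 16 of 21 (1.93e-08), astrocytes, 9 of 10 (0.000326), myelin, 7 of 7 (0.00279), and the metabolic lists of oxidative phosphorylation (0.000141), cholesterol synthesis (0.00025), glycolysis (0.000459) and fatty acid synthesis (0.0253). With an estimated correlation these had adjusted p = 0.0570, 0.181, 0.399, 0.448, 0.361, 0.181 and 0.210, in that order. With the bird as a block, immediate early genes (0.0347) and the interferon response (0.00151) also passed, both higher in the pituitary, against 0.0659 and 0.0598 without it. With an estimated correlation and no block they had adjusted p = 0.454 and 0.735.

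Pituitary libraries differed widely in genes better known from other tissues, which were chosen after their values were seen (CPM scaled over all 16 libraries). AGRP, an appetite peptide of the arcuate nucleus, stood at 30.1, 56.4 and 27.1 CPM in the pituitaries of birds 38, 40 and 50, and at 0.77 to 3.03 CPM in the others. In the hypothalami of birds 38, 40 and 50 AGRP was lower than in their pituitaries, at 12.4, 21.9 and 5.80 CPM. ACTA1 and TNNC2, genes of the skeletal muscle sarcomere, reached 647 and 282 CPM in the pituitary of bird 50, and the next highest library, that of bird 38, had 147 and 58.8 CPM.

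**Figure D1:**
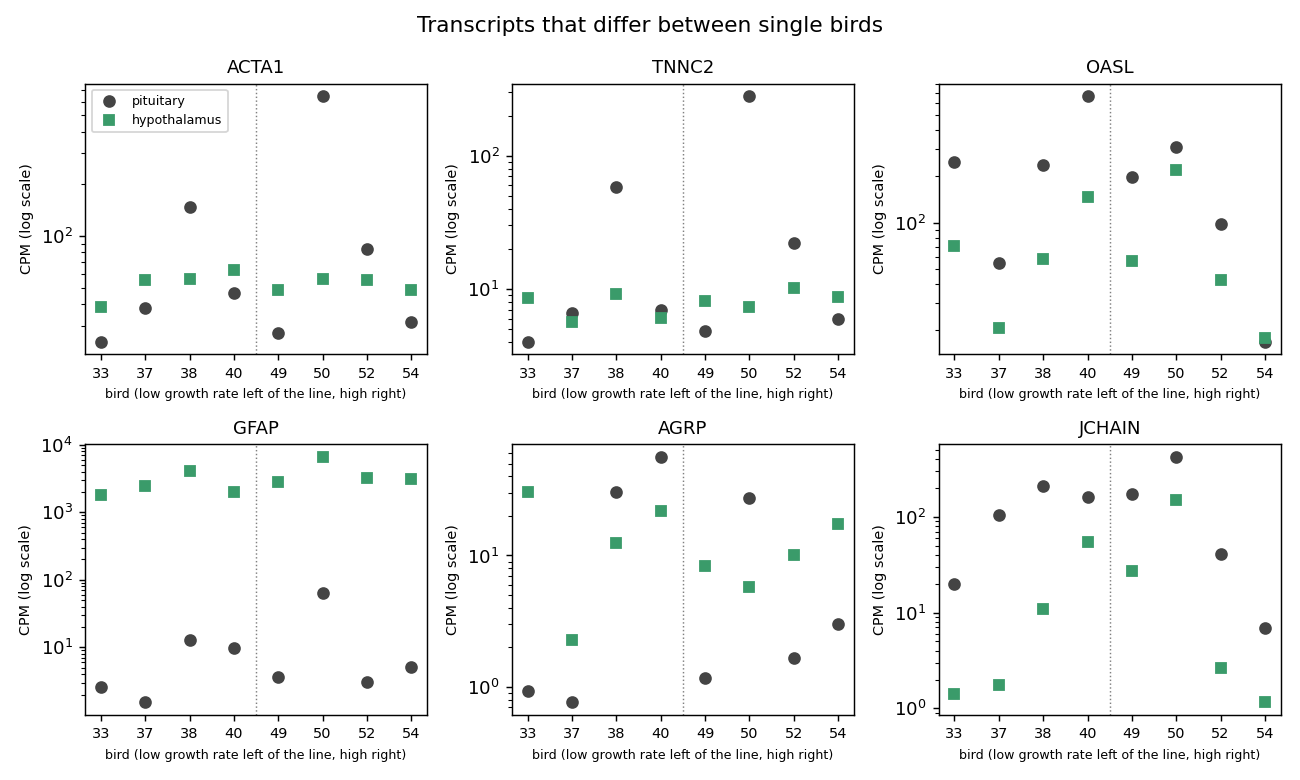
CPM (log scale, scaled over all 16 libraries) of 6 genes in each bird; circles are pituitary and squares hypothalamus libraries, with the 4 birds of low growth rate left of the dotted line. The muscle genes ACTA1 and TNNC2 peak in the pituitary of bird 50, at 647 and 282 CPM, and among the pituitaries AGRP is highest in birds 38, 40 and 50.

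In the pituitary, LHFPL5 and HMOX1 separated birds of low and high growth rate most clearly, and neither passed edgeR's test over all genes. LHFPL5 (ENSACDG00005004119, protein-coding, scaffold KZ155896.1, 5329569 to 5333945), a tetraspan membrane protein known from the mechanotransduction complex of hair cells, stood at 10.7 ± 1.76 CPM at low and 3.65 ± 0.69 CPM at high growth rate (SD, n = 4 each), a log2 difference of -1.55 ± 0.22 (SE). HMOX1 (ENSACDG00005017735, protein-coding, scaffold KZ156030.1, 365603 to 371316), the enzyme that breaks down heme, stood at 73.4 ± 2.58 CPM and 125 ± 16.8 CPM, a difference of 0.77 ± 0.11. Both had an adjusted p of 0.292 in edgeR. The other genes with the smallest p at higher level in fast growers were DCC, the netrin receptor (0.91 ± 0.16), DNLZ (0.74 ± 0.14), CALB2, the calcium-binding protein calretinin (0.59 ± 0.14) and LYSMD1 (1.10 ± 0.26). At lower level were ALDH1A1, an enzyme that makes retinoic acid (-0.79 ± 0.18), GFRA3 (-0.84 ± 0.22), ADAMTSL3 (-0.59 ± 0.15) and ANO6, a phospholipid scramblase (-0.41 ± 0.11). All of these had an adjusted p of 1.00 in edgeR.

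**Figure D2:**
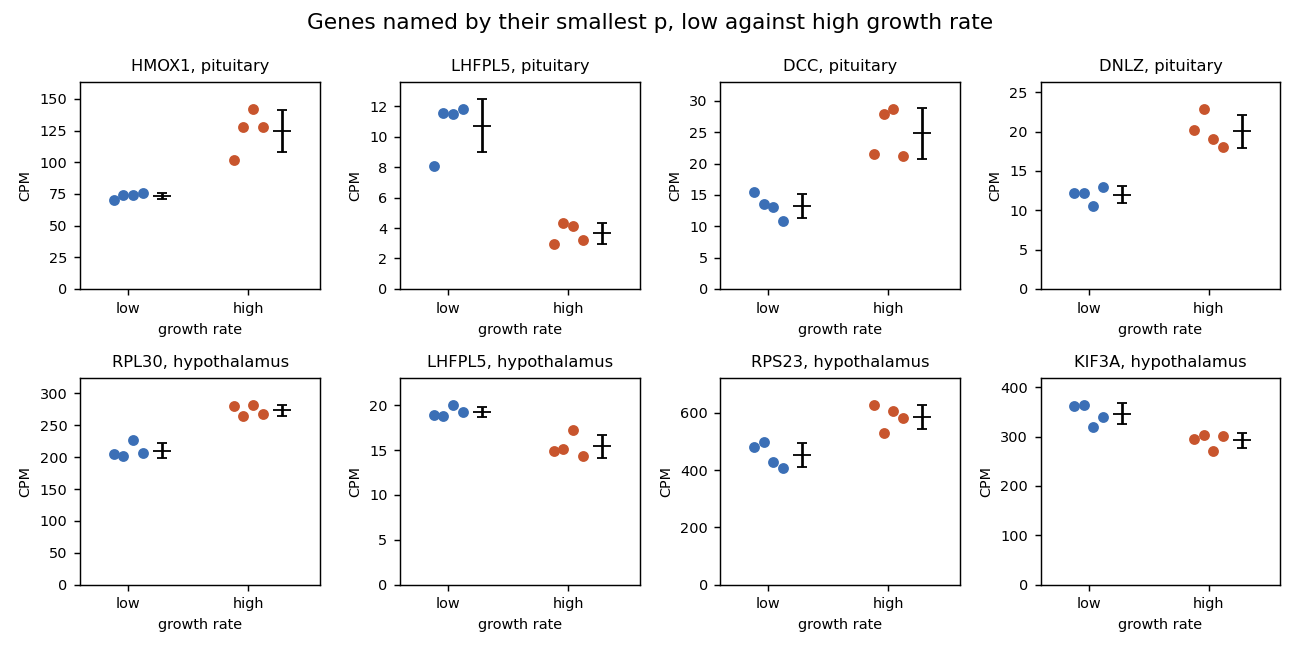
CPM of 8 genes by growth rate; points are birds (4 per group) and the bars beside them the mean and SD. In the pituitary (top) LHFPL5 lies at 8.11 to 11.8 CPM at low and 2.92 to 4.36 CPM at high growth rate, and in the hypothalamus (bottom) RPL30 is higher and LHFPL5 lower in all 4 birds of high growth rate.

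With edgeR, 0 of 13471 genes passed in the pituitary. At an unadjusted p under 0.05 there were 266 genes, where chance alone would give 674, and 195 genes had no overlap between groups, or 1.45% where chance gives 2.86%. The DESeq2 Wald test called 4 genes, in which LHFPL5 fell (adjusted p of 3.27e-06) and HMOX1 (3.82e-06), DCC (0.00393) and DNLZ (0.00445) rose. Limma voom called 0, and an edgeR fit over all 16 libraries called LHFPL5 alone (0.000594). That fit had no bird term and shared its dispersion between tissues. The biological coefficient of variation was 0.161 in the hypothalamus against 0.253 in the pituitary.

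No pituitary hormone gene passed. POMC stood at 26303 ± 5951 CPM at low and 35022 ± 6527 CPM at high growth rate (log2 difference 0.41 ± 0.19), PRL at 22345 ± 9642 and 25245 ± 12547 CPM (0.18 ± 0.39) and CGA at 24966 ± 10915 and 21290 ± 10826 CPM (-0.23 ± 0.40). Among these 3 genes, 0 passed when adjusted over the list alone, as over all genes, and POMC was nearest with 0.172. The signs of PRL and CGA were not settled: without bird 54 PRL read -0.21 and without bird 38 -0.051, and without bird 40 CGA read 0.081. Growth hormone had no named gene in the main table. Its assembled transcript, whose best protein match was duck growth hormone at 98.6% identity, stood at 37880 ± 14315 estimated CPM at low and 34015 ± 8436 at high growth rate (-0.12 ± 0.31, adjusted p of 1.00), and the difference turned to 0.17 without bird 37 and 0.029 without bird 54. DIO2, the deiodinase that activates thyroid hormone (0.50 ± 0.17), and TAC1, the precursor of substance P (1.40 ± 0.52), had the largest differences relative to their errors among the assembled genes, both at 0.154 when adjusted over that list alone. Assembled POMC (0.41 ± 0.16) had the same adjusted value. TAC1 was scarce, at 1.73 ± 0.82 estimated CPM at low and 4.58 ± 3.10 at high growth rate, where bird 54 reached 9.04. LHB, the subunit of luteinising hormone, differed by 0.26 ± 0.35.

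**Figure D3:**
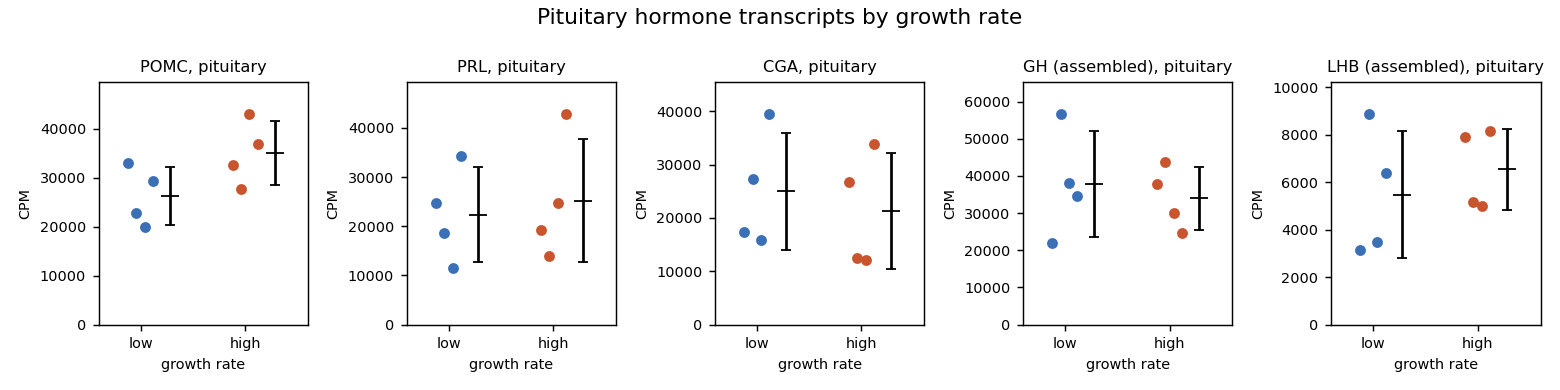
Pituitary hormone transcripts by growth rate, in CPM for POMC, PRL and CGA and in estimated CPM for assembled GH and LHB; points are birds (4 per group) and the bars beside them the mean and SD. The groups overlap in all 5 panels.

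Of the 38 lists, 6 passed in the pituitary by limma's camera. Cytoplasmic ribosomal protein genes rose, with 54 of 56 members higher at high growth rate and a median of 0.13 on the log2 scale (adjusted p of 4.19e-19), among them RPS15 (0.32 ± 0.08) and RPL36 (0.32 ± 0.11). Oxidative phosphorylation genes rose with 41 of 42 members higher (median 0.16, 1.22e-12), such as NDUFS5 of complex I (0.38 ± 0.12), and mitochondrial ribosomal protein genes with 47 of 52 (0.11, 8.86e-06), such as MRPL37 (0.28 ± 0.09). Circadian clock genes fell, with 10 of 14 lower (-0.18, 0.00436), where the repressors BHLHE40 (-0.60 ± 0.16), PER3 (-0.41 ± 0.15) and PER2 (-0.40 ± 0.14) were lower and their activator ARNTL was at 0.21 ± 0.09. Interferon response genes fell with 15 of 16 lower (-0.34, 0.000571), such as PARP12 (-0.36 ± 0.17), and genes of folliculostellate and stem-like cells with 10 of 10 lower (-0.19, 0.0138), among them ALDH1A1 and SOX2 (-0.28 ± 0.13). With an estimated correlation none of the 6 calls held: adjusted p = 0.353 for the cytoplasmic ribosomal, oxidative phosphorylation and circadian lists, 0.871 for the mitochondrial ribosomal and interferon lists and 0.800 for the folliculostellate list.

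Over all genes, 0 members of these lists passed edgeR's test, and adjusted over the list alone 1 did, a member of the folliculostellate list that was lower at high growth rate. Without bird 38, 10 lists passed in place of 6, and without bird 40 or bird 54, 4. Without bird 54 the circadian list (0.102) and the interferon list (0.318) no longer passed by camera. The interferon list (0.257) was also lost without bird 40, and the folliculostellate list without bird 40 (0.378), 49 (0.149) or 52 (0.0724) and in the ENSABRG gene table (0.145). The interferon score was highest in bird 40, at 0.78, and lowest in bird 54, at -1.04, a range within each group wider than the difference of -0.40 between groups. Genes of GH and IGF signalling did not pass as a list (0.452), with 3 of 22 members at an unadjusted p under 0.05, all higher: CISH, a target of growth hormone signalling (0.82 ± 0.25), IRS2 (0.93 ± 0.38) and IGFBP7 (0.27 ± 0.11). The skeletal muscle list did not pass either (0.120), with 7 of 7 members higher at high growth rate, and its score was highest in the pituitary of bird 50, at 2.82.

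In the hypothalamus, RPL30, a ribosomal protein gene, had the smallest p. It stood at 210 ± 11.8 CPM at low and 274 ± 8.48 CPM at high growth rate (SD, n = 4 each; log2 difference 0.38 ± 0.07, SE), and the ribosomal protein genes RPL29 and RPS23 differed by 0.39 ± 0.08 and 0.37 ± 0.09. RNH1, the ribonuclease inhibitor (0.34 ± 0.08), and NGLY1, which removes sugar chains from misfolded glycoproteins (0.36 ± 0.08), were also at higher level. LHFPL5, as in the pituitary, was at lower level (-0.32 ± 0.10), together with SARM1, an enzyme of axon degeneration (-0.32 ± 0.09), DNM3, a dynamin (-0.27 ± 0.08), KIF3A, a kinesin motor subunit (-0.25 ± 0.07) and ANKRD24 (-0.36 ± 0.11). None passed over all genes, each with an adjusted p of 0.998 in edgeR.

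With edgeR, 0 of 13695 genes passed in the hypothalamus, with 456 at an unadjusted p under 0.05 where chance would give 685, and 271 without overlap between groups, or 1.98% where chance gives 2.86%. DESeq2 called 2, in which RPL30 rose (adjusted p of 0.000121) and 1 unnamed gene fell, and limma voom called 0. Of the appetite genes, 0 of 7 passed over all genes and 0 adjusted over the list alone. POMC, whose peptides curb feeding, differed by -0.05 ± 0.25, AGRP, whose peptide drives it, by -0.69 ± 0.58, LEPR, the leptin receptor, by -0.37 ± 0.28, and INSR, the insulin receptor, by -0.16 ± 0.10. CNR1 (-0.04 ± 0.12), GLP1R (-0.09 ± 0.25) and NPY5R (0.08 ± 0.14) lay within their errors of 0. AGRP kept its sign in edgeR but moved to -0.25 without bird 33 and to -1.06 without bird 37 or 54. LEPR moved to -0.12 without bird 40, -0.22 without bird 50 and -0.56 without bird 54, and INSR to -0.10 without bird 37. The sign of POMC turned without bird 38 (0.0032), 40 (0.043), 49 (0.11) or 52 (0.029), that of CNR1 without bird 33 (0.021) or 37 (0.016), that of GLP1R without bird 33 (0.058) or 37 (0.0071), and that of NPY5R without bird 38 (-0.010). No releasing hormone had a named gene in the main table. Among the assembled transcripts, somatostatin, the inhibitor of growth hormone release, stood at 495 ± 71.9 and 508 ± 69.98 estimated CPM (0.06 ± 0.15), and its sign turned without bird 38 (-0.036) or 50 (-0.0019).

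Of the 38 lists, 8 passed in the hypothalamus by limma's camera. Cytoplasmic ribosomal protein genes rose with 54 of 56 members higher (median 0.23, adjusted p of 1.44e-38), 33 of them at an unadjusted p under 0.05 and 6 adjusted over the list alone, against 0 over all genes. RPL31 differed by 0.42 ± 0.10. Oxidative phosphorylation genes rose with 39 of 42 higher (0.10, 2.51e-08), such as NDUFS5 (0.31 ± 0.10), mitochondrial ribosomal protein genes with 47 of 52 (0.10, 2.51e-08), and microglia and macrophage genes with 10 of 10 (0.58, 0.00689), such as CX3CR1 (0.82 ± 0.40) and C1QB (0.71 ± 0.33). Heat shock genes fell with 15 of 16 lower (-0.11, 0.000331), such as BAG3 (-0.27 ± 0.10), neuronal genes with 11 of 13 (-0.09, 0.00864), such as the neurofilament NEFH (-0.42 ± 0.15), genes of GABA and glutamate synapses with 17 of 21 (-0.08, 0.0115), such as GAD1 (-0.28 ± 0.14), and immediate early genes with 11 of 15 (-0.20, 0.0237), such as FOS (-0.39 ± 0.24). With an estimated correlation none of the 8 calls held: adjusted p = 0.533 for the cytoplasmic ribosomal, heat shock and neuronal lists, 0.779 for the oxidative phosphorylation and mitochondrial ribosomal lists, and 0.817 for the microglia, synapse and immediate early lists.

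Without bird 54, 13 lists passed in place of 8. The microglia score was highest in bird 50, at 1.26 against -0.51 to 0.28 in the other 7 birds, and without that bird the list no longer passed (0.818), nor without bird 33 (0.199). The synapse list was lost without bird 33 (0.218), 37 (0.260) or 52 (0.153), and the neuronal list without bird 54 (0.0653). The immediate early list was lost without bird 37 (0.0713), 38 (0.250), 49 (0.130) or 50 (0.122) and in the ENSABRG gene table (0.121). In the hypothalamus score of cytoplasmic ribosomal proteins, birds of high growth rate stood at -0.01 to 0.19 and those of low growth rate at -0.29 to -0.01. A two-sided exact permutation test of that score gave p = 0.0571 in the hypothalamus and 0.0286 in the pituitary, the smallest it can give, and neither passed after adjustment over the 38 lists (0.543 and 0.724).

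Whether growth rate was tied to different changes in the 2 tissues was tested as an interaction. LHFPL5 had the smallest p, with a growth-rate difference in the pituitary minus that in the hypothalamus of -1.23 ± 0.21 (adjusted p of 0.451 in edgeR). The growth-rate difference was higher in the pituitary than in the hypothalamus for DCC (0.99 ± 0.23), CACNA1I, a T-type calcium channel (0.97 ± 0.22), BMP7, a growth factor (0.64 ± 0.17), SLC4A8 (0.43 ± 0.13) and KLHDC8B (0.55 ± 0.17). It was lower for CHRNA5, a nicotinic receptor subunit (-1.14 ± 0.33), ANO6 (-0.53 ± 0.16), MARCKSL1 (-0.50 ± 0.15) and FYN (-0.31 ± 0.10). Each had an adjusted p of 1.00 in edgeR. Such a contrast can come from either tissue. From low to high growth rate, mean MARCKSL1 fell from 175 to 147 CPM in the pituitary. In the hypothalamus it rose from 233 to 277 CPM. With edgeR 0 of 14394 genes passed, 206 had an unadjusted p under 0.05 where chance would give 720, DESeq2 called 1, LHFPL5 (0.000402), and limma voom 0.

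By limma's camera 5 of 38 lists differed in their growth-rate response between the tissues. The difference was lower in the pituitary for cytoplasmic ribosomal proteins (median -0.10, adjusted p of 3.85e-06), the interferon response (-0.39, 0.0223), the circadian clock (-0.18, 0.0223) and cholesterol synthesis (-0.12, 0.0391), and higher for neuronal genes (0.20, 0.0214). None held with an estimated correlation, with an adjusted p = 0.845 for the ribosomal, interferon and cholesterol lists, 0.405 for the circadian list and 0.397 for the neuronal list. With the bird as a block 8 lists passed, with inflammation (0.0175), microglia (3.43e-06) and skeletal muscle (0.0317) added, the first 2 lower in the pituitary and the last higher. Without the block, each of these 3 had an adjusted p = 0.845 with an estimated correlation. The microglia score in the hypothalamus and the skeletal muscle score in the pituitary were highest in bird 50, at 1.26 and 2.82.

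The authors' deposited table for the same gene counts called more genes, 51 in the pituitary and 62 in the hypothalamus at an adjusted p under 0.05. Among named genes, the smallest adjusted p-values for the pituitary in the authors' deposited table were those of TNNC2 (log2 difference 2.05), ACTA1 (1.63), Metazoa_SRP, an RNA of the signal recognition particle (2.11), PFKM, the muscle phosphofructokinase (1.88) and, tied, MX2, an interferon-induced gene (-1.33), and GFAP (1.51). Among named genes of the hypothalamus the authors' deposited table led with JCHAIN, a chain of secreted antibodies (1.41), RIDA (1.19), SCIN (0.92), HLA-DRA, an antigen-presenting molecule (0.81) and SLC26A1 (-0.76). With edgeR 0 of these calls passed, and 22 of the 51 and 14 of the 62 had an unadjusted p under 0.05. In 9 of the 51 and 2 of the 62 the groups did not overlap. Leaving out 1 bird at least halved the difference of 27 of the 51 and 42 of the 62, and bird 50 was that bird for 15 and 23. These differences are of mean log2 CPM and not on the scale of the log2 values in the authors' deposited table. Without bird 50 they went from 1.01 to -0.24 for TNNC2, from 0.73 to -0.26 for ACTA1, from 0.89 to -0.18 for PFKM, from 0.70 to -0.30 for GFAP, from 0.76 to -0.50 for JCHAIN, from 0.39 to -0.26 for SCIN and from 0.58 to 0.066 for HLA-DRA. Metazoa_SRP went from 1.37 to 0.62 without bird 49, MX2 from -1.15 to -0.61 without bird 54, SLC26A1 from -1.01 to -0.18 without bird 52, and RIDA from 1.06 to 0.84 without bird 49. LHFPL5 (-1.56) and HMOX1 (0.77), chosen here for their edgeR values, were also called in the authors' deposited table for the pituitary.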

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

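The tests of muscle genes and of depth were chosen after the patterns and the library values behind them had been seen, while those of matched genes, ruminant matches and other splits of the birds were set before the values they measure, though after the patterns themselves were known.

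Among 262 groups of libraries examined, 27 held a library far from the rest, and birds 50 and 38 accounted for 8 each. For independent, normally distributed values chance would give about 1 in 20, or 13.1. The items examined do not meet this: they are largely CPM, some are genes the authors called, and several repeat 1 signal. The count is therefore no test of an excess. Values are CPM scaled within the tissue, unless stated, and estimated CPM for assembled genes.

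Muscle genes led the authors' deposited table for the pituitary, and the pituitary of bird 50 stood far above the other 3 birds of high growth rate, with TNNC2 at 264.9 CPM (others 4.58 to 20.7), ACTA1 at 608 CPM (25.7 to 78.1) and PFKM at 46.8 CPM (1.32 to 4.85). Of the 7 measured skeletal muscle genes, 6 peaked in that library, and the median log2 difference of the list went from 1.24 to -0.67 without that bird, as such a peak implies. Of 14 other muscle genes, outside that list and the authors' calls, 8 peaked in that library too (one-sided exact binomial p of 8.86e-05, genes not being independent), and the 14 lay a median of 0.54 above the other birds' median on the log2 scale, so muscle tissue in that library is a candidate explanation. The skeletal muscle score did not separate the growth groups (two-sided exact permutation p of 0.6), which leaves an effect of growth rate open at 4 birds per group. The pituitary of bird 38, at low growth rate, had TNNC2 at 54.9 CPM against 3.77 to 6.59 in the other 3.

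Cytoplasmic ribosomal protein genes were higher at high growth rate in both tissues, which came from the same birds and are not independent. With the log2 library total as a covariate, the growth-rate difference of the list score was 0.15 in the pituitary (95% interval 0.017 to 0.29), from 0.14 without it, and 0.37 in the hypothalamus (0.17 to 0.57), from 0.23, which argues against a linear trend with depth as the whole cause, though the pituitary interval came close to 0. The list median was 0.13 in the pituitary and 0.23 in the hypothalamus. It lay at percentile 100 among 10000 random sets matched on gene span and expression in each tissue. Genes of these sets were drawn singly, which ignores that ribosomal protein genes move together, so the percentile is too extreme to weigh. The matched sets had medians of 0.04, so the trend seen in matched genes was smaller than the list difference. A chance arrangement of birds stays open, since the list calls were lost with an estimated correlation and other splits gave as many lists. Growth rate itself may or may not be behind the list difference. RNA quality, dissection and batch were not tested and stay open too.

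Assembled transcripts whose best protein matches were ruminant stood out in bird 40. The transcript matching cattle TCTP, a translationally controlled tumour protein, was at 20.9 in its pituitary (next highest 2.34) and 10.5 in its hypothalamus (2.09), and the one matching goat HBBA, a beta globin, at 40.8 in its hypothalamus (2.64). Of 20 assembled genes with a close ruminant match, 2 peaked in that hypothalamus library (one-sided exact binomial p of 0.358) and 1 in the pituitary of bird 40, while 5 peaked in the pituitary of bird 33 and 3 in that of bird 50. The 20 include HBBA, which prompted the test. A close match alone does not tell a ruminant transcript from a goose gene of a conserved protein. The count could therefore not decide on ruminant RNA in that library, and no biological explanation was tested.

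Other splits of the same birds into groups of 4 did not exclude chance for the lists. In the pituitary 26 of 35 splits called at least the real 6 lists, and the highest other 15, and in the hypothalamus 17 of 35 called at least the real 8, and the highest other 18. For genes the real splits called 0, which all 35 of 35 splits reach by construction, so their counts say nothing about chance. The highest other split called 117 genes in the pituitary, 7 in the hypothalamus and 118 in the interaction, and the median of the others was 0 in each. The highest pituitary and interaction splits set birds 33, 37, 49 and 52 against 38, 40, 50 and 54. Such a maximum over the other splits was not tested against chance, so it does not establish a structure of the samples other than growth rate. In the pituitary 7 of 38 list scores parted birds 33, 37, 49 and 52 from the others without overlap. Among them were astrocytes (-0.61 to -0.29 against -0.028 to 0.85) and folliculostellate and stem-like cells (-0.38 to -0.060 against 0.022 to 0.69). A split fixed in advance would give 1.09 by chance. This split was singled out after its gene counts were seen, in the same libraries, so 1.09 is no valid expectation for it. What lies behind the split was not tested. For the tissues 1 of 100 splits, the real one, reached the 4941 genes of a fit on tissue alone. That is the smallest share that 100 splits can give. The other splits mix libraries of the tissues, so this outcome says little beyond the known difference between them. The 49 other splits that also parted the libraries of all 8 birds called at most 3092.

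Single libraries also stood apart in the following values. In the pituitary at low growth rate bird 33 had CALB2 at 119.9 and LHFPL5 at 8.11 CPM, bird 38 an endocrine cell score of -0.38, and bird 37 assembled TAC1 at 0.507. At high growth rate bird 49 had Metazoa_SRP at 58.1 CPM, bird 54 the lowest total, at 8.54 M counts, and bird 50 assembled SST at 23.3, AGRP at 24.2 and DIO3, the deiodinase that inactivates thyroid hormone, at 39.6. Over all 8 pituitaries bird 50 had the highest GFAP, 63.9 CPM (scaled over all libraries). In the hypothalamus at low growth rate bird 40 had SCIN at 92.7 CPM, and bird 38 a score of hypothalamic nuclei of -0.23, assembled GH at 90.8 and LHB at 14.2, and the lowest assembled SST, at 386.9. At high growth rate bird 54 had GLP1R at 41.0 CPM and assembled CCK at 611.9, and bird 52 had the lowest NPY5R, at 14.05 CPM. Over all 8 hypothalami, scaled over all libraries, bird 38 had the highest PRL (32.9 CPM) and CGA (57.2 CPM), bird 40 SIX2 (9.03 CPM), bird 50 GFAP (6658 CPM) and bird 33 SLC6A11 (340.5 CPM).

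The growth-rate difference itself differed between the tissues by limma's camera for cytoplasmic ribosomal proteins (adjusted p of 3.85e-06), the interferon response (0.0223), the circadian clock (0.0223) and cholesterol synthesis (0.0391), each lower in the pituitary, and for neuronal genes (0.0214), higher there. None of the 5 held with an estimated correlation.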

How the results depend on the processing

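The fit without birds 40 and 50, the fit with a principal component and all values of assembled genes were chosen after seeing the data. The gene counts of the growth comparisons stayed at 0 with DESeq2 size factors, no filter, limma voom, the ENSABRG and de novo tables, the replicate block, the principal component and without any single bird, while DESeq2's Wald test called 4 genes in the pituitary and 2 in the hypothalamus, and the fit on all 16 libraries 1 in the pituitary. For the interaction it was 1 with DESeq2, 1 with kallisto and 49 with Salmon (12 higher and 37 lower in the pituitary), and 0 under the other settings. The number of genes differing between pituitary and hypothalamus, 4948, ran from 4919 to 5012 without single birds and was 4971 with the bird as a block. It was 2113 at a fold of at least 4, and 30399 and 36622 in the kallisto and Salmon tables, which hold more genes. Beyond more genes tested and a stricter fold, the cause was not tested. DESeq2 gave no adjusted p for GFAP between tissues, so it has no verdict there. List counts were 0 in both tissues with an estimated correlation and with fry, directional or mixed; without single birds they ran from 4 to 10 in the pituitary and 6 to 13 in the hypothalamus, and they were 8 and 6 without birds 40 and 50. Replicate numbers of low and high birds are different animals, whose deviations correlated at 0.396, -0.246, -0.123 and 0.0855 in the pituitary and 0.0303, -0.216, 0.101 and -0.111 in the hypothalamus, with 1 of 4 best with its own number in each tissue; that replicate block gave 8 and 11 lists and 0 genes. Beside the lists printed with the tissue and interaction results, the bird block changed no list call and no call of a tissue or interaction gene given above, and it shared 2750 of the 2789 gene names among the tissue calls. Lists were not run in the de novo tables, where 61.6% and 58.6% of pituitary list members were found. Signs turned for GLP1R in the kallisto (0.015) and Salmon (0.018) tables and for SARM1 (0.028 and 0.038). Without birds 40 and 50 they turned in the pituitary for CGA (0.27) and assembled CGA (0.16), DIO3 (-1.38), PENK (0.52), SST (-1.53) and a neurophysin matched as NEU1 (-0.0019), and in the hypothalamus for LEPR (0.028), POMC (0.066) and assembled POMC (0.029); SST in the pituitary also turned with limma voom (-0.034). Without single birds, differences in the pituitary ran for PRL from -0.21 to 0.46, for CGA from -0.55 to 0.081, and for the assembled genes from -0.44 to 0.021 (CGA), -0.32 to 0.17 (GH), -0.17 to 1.16 (CCK), -1.33 to 1.86 (DIO3), -0.63 to 0.90 (PENK), -2.58 to 1.37 (SST) and -0.83 to 0.29 (TTR). In the hypothalamus they ran from -0.34 to 0.11 for POMC, -0.14 to 0.021 for CNR1, -0.30 to 0.058 for GLP1R and -0.010 to 0.18 for NPY5R, and for assembled genes from -0.56 to 0.41 (CGA), -0.024 to 0.17 (DIO2), -1.13 to 0.28 (LHB), -0.32 to 0.14 (POMC) and -0.036 to 0.17 (SST). The cause of these turns was not tested. Of the other values of single genes under the alternatives set beforehand, 887 kept their direction and side of the threshold and 7 passed it.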

Other observations

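All values in this part were chosen after they had been seen and no test was run on them. Immune genes varied widely between birds in both tissues, in CPM scaled over all 16 libraries. OASL, an interferon-induced antiviral gene, was at 666 CPM in the pituitary and 146 CPM in the hypothalamus of bird 40, at 311 and 220 CPM in bird 50, and at 16.9 and 17.8 CPM in bird 54. JCHAIN, a chain of secreted antibodies, was at 424 and 151 CPM in bird 50 and at 6.94 and 1.16 CPM in bird 54, both at high growth rate. CSF1R and C1QC, genes of microglia and macrophages, were at 151 and 47.9 CPM in the hypothalamus of bird 50, against 48.1 to 93.7 and 12.6 to 24.6 CPM in the others.

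Assembled peptide genes varied within groups as well. PENK, the precursor of enkephalins, was at 128, 252, 160 and 219 estimated CPM in the pituitaries of birds 38, 40, 50 and 54, and at 15.3 to 22.5 in the other 4. TTR, a carrier of thyroid hormone made by the choroid plexus, was at 192.0 in the hypothalamus of bird 54 and at 9.44 to 61.7 in the others. TNC, an extracellular matrix gene, was at 104.5, 63.9, 72.8 and 43.4 CPM in the pituitaries of birds 38, 40, 50 and 54 and at 1.34 to 15.3 CPM in the other 4.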
